A study of Gossypium bickii with 18 samples.

How the data were processed

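RNA was measured in cotyledons of Gossypium bickii, an Australian diploid cotton. There were 18 libraries in 6 groups of 3. The 0 h group has no light condition in the labels. The others were 12, 24, 36 and 48 h after imbibition (water uptake, which starts germination) under light, and 24 h in the dark. Groups and replicate numbers were taken from the sample labels. The labels call the replicates biological but do not say whether they came from separate plants or seed lots. Every p-value from a comparison of libraries therefore measures only the spread between these samples. The permutation p-values for neighbouring gene IDs come from random draws of genes instead.

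Per the labels' protocols, total RNA was made into libraries with the NEBNext Ultra RNA kit and sequenced paired-end on an Illumina instrument. Trimmomatic 0.36, HISAT2 2.0.4 and HTSeq 0.6.0 are named in the submitters' processing notes, with no settings. The genome build, the annotation and the strand setting are not given in the sources used here. The values used are FPKM (fragments per kilobase of gene scaled to the mapped fragments of the library), as deposited by the authors in 2 tables, per the file headers. The time-course table holds 15 libraries and 43790 gene IDs. The light-dark table holds 6 libraries and 49301 gene IDs, of which 5511 do not start with Gbi and do not occur in the other table. No column of per-sample values was left unused.

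The files do not pair gene IDs with gene names, and no reference was at hand. Genes are therefore given by ID, and of 19 gene lists written before the data were examined 0 members could be matched, so the lists were not used. The column names of the time-course table at 24 h give a time and a replicate number but not light or dark. They were taken as the 24 h light libraries because all later and earlier imbibed samples in that table are light samples and the dark samples have their own columns in the other table. The replicate deviations of those columns correlated at 0.847 to 0.852 across genes with the light columns of the same number in the light-dark table, and at -0.106 to 0.117 with the dark columns. The same 3 libraries of 24 h light thus appear in both tables with different values. Over 15986 genes at 5 FPKM or more in either table, the median log2 ratio of the light-dark table over the time-course table was 0.31, and 9.28% of genes lay more than 2-fold from that median. Of these genes, 185 stood at 5 FPKM or more in the time course and under 0.1 in the light-dark table. Values were therefore compared only within a table.

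Absolute depth cannot be read from FPKM. In the light-dark table low values fell on steps of whole fragments, and the ratio of these steps gave relative depths, against dark replicate 1, of 1.06 and 1.16 for dark replicates 2 and 3 and of 1.13, 1.07 and 1.08 for light replicates 1 to 3. No such steps were found in the time-course table, where depth stays unknown and no counting interval is given.

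Tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using a group-means model, moderated variances with a mean-variance trend and Benjamini-Hochberg adjustment over all genes tested. Genes with at least 1 FPKM in at least 3 libraries of the table were tested, which left 26086 in the time course and 23059 in the light-dark table. A gene was called when its adjusted p was under 0.05 and its absolute log2 difference was at least 1. All tests were two-sided. The 5 times were fitted together and shared an estimate of the spread, and the light-dark table was fitted by itself. A moderated F test asked for any difference among the 5 times, with a range of group means of at least 1. Called genes were then sorted by the time of their highest mean. Log2 differences are on the log2(FPKM + 1) scale, which understates changes of genes with low values. A value of 0 may be a failed estimate, so such genes are described as listed at 0 with each library's value.

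The number of genes at 1 FPKM or more and the share of summed FPKM in the 100 highest genes were compared with exact permutation tests, two-sided, for which 3 against 3 libraries cannot give a p below 0.1. The light response was set against the change from 12 h to 48 h across genes, since those comparisons share no library. Genes are not independent replicates, so no p-value is given for that relation. By a rule fixed before the data were examined, the genes named were those with the largest log2 difference among called genes whose replicates did not overlap and whose higher mean was at least 10 FPKM, 2 per direction and comparison. The gene with the highest mean in each group was also named. For each library, genes at least 2 log2 units above or below both other libraries of its group were counted, which was decided after the data were seen.

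The steps were tested on simulated data made from the real means and spreads, with 200 changed genes. The changed genes were drawn from those with a mean log2 value of at least 4, so recovery at lower levels was not tested. For 12 h against 0 h, among 26086 simulated genes, 95% of the changes of 2 log2 units were called. Of the changes of 1 log2 unit, 61% passed the adjusted p in the right direction, with no fold minimum applied. Of 25886 unchanged genes, 6 were called. For light against dark, among 23059 simulated genes, these values were 87%, 43% and 4 of 22859. The alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, the replicate number as a block (given with the other alternatives), each library left out, no fold minimum, and a fit of only the 2 groups compared. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.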

Results

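Transcript levels were followed in cotyledons of Gossypium bickii from 0 h to 48 h after imbibition, and seed kept in the dark for 24 h was compared with seed under light. The series was set up to profile expression along germination and under dark and light. Each of the 6 groups had 3 libraries, and values were FPKM from 2 tables made separately by the authors. Genes are given by the IDs in the files, which do not pair them with names.

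The cotyledon transcriptome became broader after imbibition. At 0 h, 17218 ± 547 genes (SD, n = 3) stood at 1 FPKM or more, against 21091 ± 230 at 12 h, 22372 ± 85.7 at 24 h, 23077 ± 224 at 36 h and 23466 ± 392 at 48 h. The 100 highest genes of each library held 36.3% ± 2.21 of summed FPKM at 0 h (SD, n = 3), 22.2% ± 1.82 at 12 h, 17.9% ± 0.518 at 24 h and 15.4% ± 1.22 at 36 h, then 20.03% ± 1.61 at 48 h. Gbi10G0039 was the highest gene at 0 h, at 30130 ± 5955 FPKM or 5.01% of the total, and averaged 5.45 ± 3.42 FPKM at 48 h (n = 3). At later times the highest gene was Gbi09G2338 at 12 h (6261 ± 1030 FPKM), Gbi10G1092 at 24 h (5037 ± 653), Gbi03G0170 at 36 h (5384 ± 711) and Gbi11G2017 at 48 h (10251 ± 2688; all SD, n = 3). Every pair of consecutive times gave the smallest p that 3 against 3 libraries allow in the exact permutation test on both measures (p = 0.1, adjusted 0.109 over 12 tests), except the number of genes at 48 h against 36 h (p = 0.2, adjusted 0.2). Across genes, log2 values of libraries at 0 h correlated with those at 12 h at a median r of 0.673 and with those at 48 h at 0.362, against 0.968 between libraries at 0 h.

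**Figure D1:**
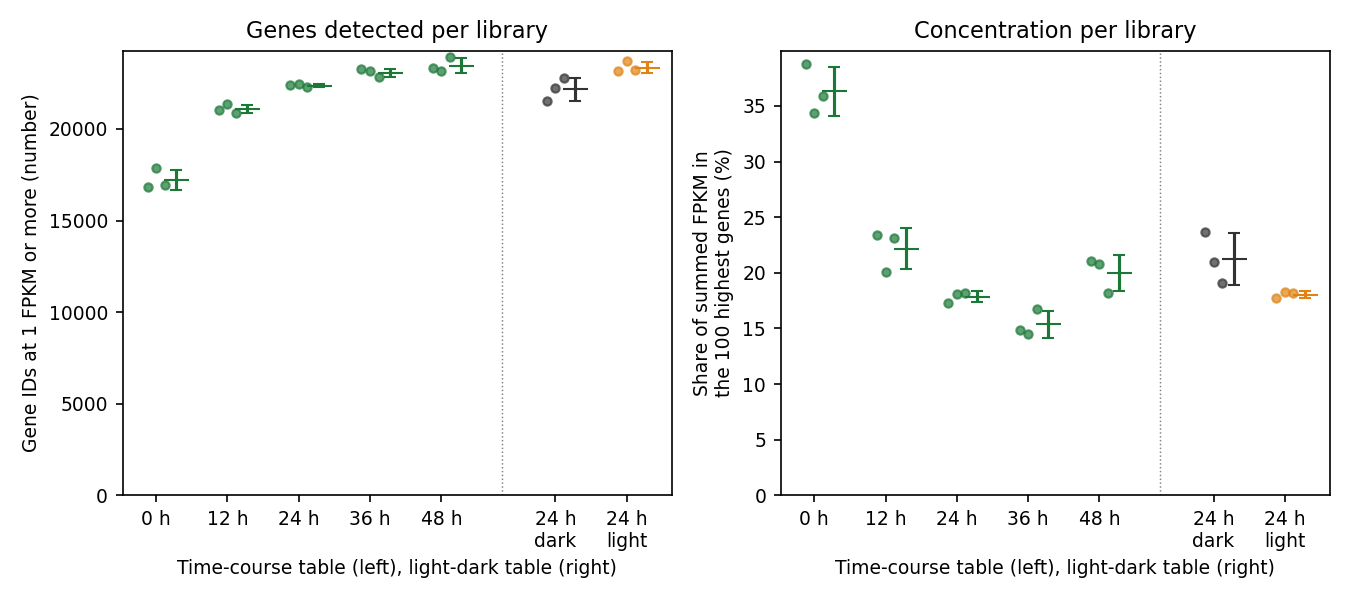
Genes at 1 FPKM or more (left panel, number) and share of summed FPKM in the 100 highest genes (right panel, percent). Points are libraries, horizontal marks with bars are group means ± SD (n = 3), and the dotted line parts the time-course table from the light-dark table. The 0 h libraries lie lowest on the left and highest on the right.

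Of 26086 genes tested over the 5 times, 20521 (78.7%) changed in the F test. The 4143 genes with their highest mean at 0 h made up 66.4% ± 2.22 of summed FPKM at 0 h, 14.0% ± 0.830 at 12 h and 8.40% ± 0.910 at 48 h (SD, n = 3). The 8354 genes highest at 48 h went the other way, from 4.82% ± 0.335 at 0 h through 19.7% ± 3.36 at 36 h to 54.3% ± 3.73 at 48 h. Between them lay 3474 genes highest at 12 h, 1943 at 24 h and 2607 at 36 h, whose shares at their own times were 39.0% ± 1.66, 18.3% ± 0.605 and 22.7% ± 0.618. Each class peaks at its own time by construction. Genes with the lowest mean at 0 h numbered 12566, or 61.2% of those that changed. Times of highest and lowest mean were taken from FPKM as deposited and not from other scalings. The direction of calls against 0 h depended on scaling, as given below, so these class sizes may too. Gbi09G1925 and Gbi09G2393 in the plot of 6 gene IDs belonged to the 0 h class, and Gbi11G2017 and Gbi07G2774 to the 48 h class.

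**Figure D2:**
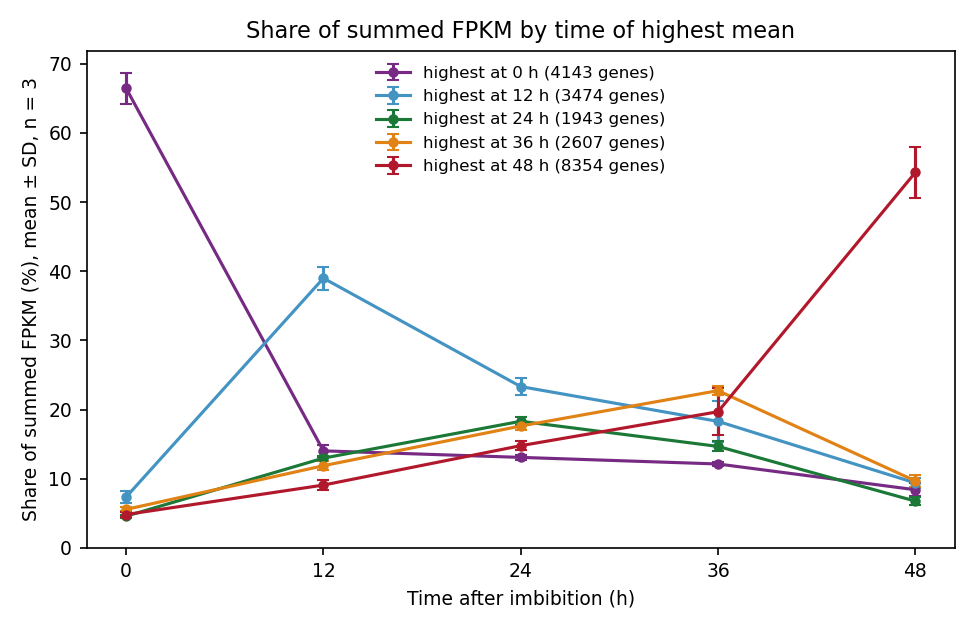
Share of summed FPKM (percent) against hours after imbibition for the genes that changed over time, split by the time of their highest mean. Points are means and bars are SD over 3 libraries. The 0 h class drops from 66.4% to 14.0% by 12 h, and the 48 h class rises from 19.7% at 36 h to 54.3% at 48 h.

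**Figure D3:**
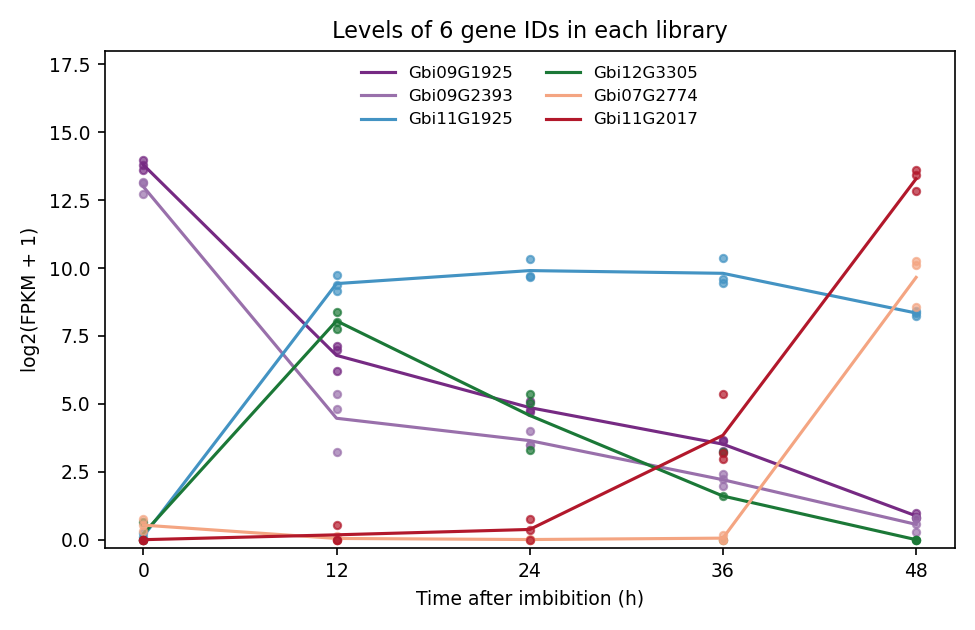
Levels of 6 gene IDs as log2(FPKM + 1) against hours after imbibition. Points are the 3 libraries of each time and lines join their means. Gbi09G1925 and Gbi09G2393 fall from 0 h, Gbi11G1925 and Gbi12G3305 are high at 12 h, and Gbi07G2774 and Gbi11G2017 are highest at 48 h.

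The step from 0 h to 12 h asked what changes as germination starts. No light condition is given for 0 h, the 12 h libraries were under light, and there was no dark group at 12 h. Imbibition and light therefore cannot be told apart in comparisons with 0 h. It changed 10842 genes, of which 7816 rose and 3026 fell. Gbi11G1925 rose to 698 ± 146 FPKM at 12 h (SD, n = 3) from 0, 0.201 and 0.0749 in the 0 h libraries, a log2 difference of 9.31 (SE 0.25, adjusted p = 3.28e-12). Gbi13G4931 rose to 3572 ± 713 FPKM (log2 difference 9.70, SE 1.15, adjusted p = 3.63e-06), from 0.0375 and 0 in 0 h replicates 1 and 3 but 72.7 in replicate 2, and its log2 difference was 11.76 without that library. Gbi09G2393 fell by 8.53 (SE 0.39, adjusted p = 2.39e-10), from 8263 ± 1357 to 25.2 ± 16.0 FPKM (SD, n = 3). Gbi10G2252 fell by 8.55 (SE 0.35, adjusted p = 8.71e-11), from 732 ± 304 FPKM to 1.76, 0 and 1.31 in the 12 h libraries. Of the genes that rose, 5657 (72.4%) were also higher at 48 h than at 0 h, and of those that fell 2160 (71.4%) were also lower. Among all 26086 genes tested, 11514 were higher and 4236 lower at 48 h. Both comparisons use the same 0 h libraries, which by itself makes calls go the same way. The direction split depended on scaling: 72.1% of calls were higher with FPKM as deposited, 55.3% after median-of-ratios scaling and 50.1% after quantile normalization. The median of all genes lay at 0.40 log2 units as deposited, at 0.11 and -0.09 under those scalings and at 0.60 after rescaling to TPM.

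Between 12 h and 24 h, 3063 genes changed, and 2486 of these rose while 577 fell. Gbi13G1505 rose from 2.95 ± 0.903 to 344 ± 166 FPKM (SD, n = 3; log2 difference 6.37, SE 0.35, adjusted p = 3.27e-08). Gbi12G3030 rose to 78.4 ± 12.1 FPKM from 0.933, 0 and 0.408 in the 12 h libraries (log2 difference 5.82, SE 0.23, adjusted p = 3.92e-09), and averaged 327 ± 57.8 FPKM at 48 h. Gbi08G0614, which averaged 57.4 ± 16.2 FPKM at 12 h, fell by 4.68 (SE 0.31, adjusted p = 2.14e-07) to 1.23 ± 0.146 FPKM. Gbi12G3305 fell by 3.48 (SE 0.63, adjusted p = 0.000991), from 270 ± 62.2 to 27.0 ± 16.2 FPKM. Of the calls, 81.2% were higher as deposited and 66.2% after quantile normalization.

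The step from 24 h to 36 h changed the fewest genes of the time course, 824, of which 673 rose and 151 fell. Gbi01G2273 rose from 1.2 ± 0.822 to 37.8 ± 13.0 FPKM (SD, n = 3; log2 difference 4.17, SE 0.31, adjusted p = 1.22e-05) and averaged 125 ± 46.6 FPKM at 48 h. Gbi11G3287 fell by 2.94 (SE 0.37, adjusted p = 0.000603), from 160 ± 24.2 to 21.8 ± 12.2 FPKM. Gbi12G3305 again fell by 2.97 (SE 0.63, adjusted p = 0.0126), to 2.02, 0 and 8.38 FPKM in the 36 h libraries. Gbi13G0900 rose by 4.35 (SE 1.14, adjusted p = 0.0362), but its 36 h values were 21.95, 48.9 and 566 FPKM, and without replicate 3 the log2 difference was 3.00 and no longer passed (adjusted p = 0.0778). In a limma fit of these 6 libraries alone 0 genes passed, against 4944 at an unadjusted p under 0.05, and the adjusted p of these 4 genes then lay between 0.0541 and 0.170. Gbi12G3305 and Gbi13G0900 also lost their calls without 24 h replicate 2 (adjusted p = 0.0533 and 0.129), 24 h replicate 3 (0.0624 and 0.0962) or 36 h replicate 2 (0.0517 and 0.0790), and with a pseudocount of 0.1 (0.0736 and 0.0727), as did Gbi13G0900 with no filter (0.0677). The count was 529 without 24 h replicate 3, 455 without 36 h replicate 2 and 1402 without 36 h replicate 3.

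A further large change came between 36 h and 48 h, when 7067 genes changed in nearly even directions, 3867 rising and 3200 falling. Gbi11G2017 rose from 18.4 ± 18.8 to 10251 ± 2688 FPKM (SD, n = 3; log2 difference 9.44, SE 0.46, adjusted p = 1.84e-09), becoming the highest gene at 48 h. Gbi07G2774 rose to 908 ± 460 FPKM from 0.125, 0 and 0 in the 36 h libraries (log2 difference 9.60, SE 0.32, adjusted p = 8.07e-11). Gbi11G0296 fell by 6.48 (SE 0.37, adjusted p = 8.39e-09), from 104 ± 56.3 FPKM to 0, 0.00527 and 0.118. Gbi11G0279 fell by 6.25 (SE 0.38, adjusted p = 1.42e-08), from 91.2 ± 50.4 to 0.0582 ± 0.0561 FPKM. These last IDs kept a nearly fixed ratio over the 9 libraries in which Gbi11G0296 reached 5 FPKM (SD of the log2 ratio 0.0628). With a looser SD limit of 0.15, 114 of 300 random genes (38%) had a partner. How many had one at 0.0628 was not counted, so how common so steady a ratio is stays unknown. Gbi11G0296 and Gbi11G0279 stood at 205 and 0 FPKM in dark replicate 2 of the other table, so their separate levels are uncertain. Of the 7816 genes that rose by 12 h, 1407 fell in this step.

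Over the whole course, 48 h against 0 h, 15750 genes (60.4% of those tested) changed, 11514 higher and 4236 lower. Gbi09G1925 fell by 12.93 (SE 0.22, adjusted p = 2.63e-14), from 14353 ± 1795 to 0.839 ± 0.132 FPKM (SD, n = 3), passing through 113.4 ± 35.2 FPKM at 12 h. Gbi09G2393 fell by 12.43 (SE 0.39, adjusted p = 1.95e-12) to 0.494 ± 0.261 FPKM. Gbi11G2017 (adjusted p = 5.35e-12) and Gbi11G2016 (adjusted p = 3.78e-11) were listed at 0 in all 3 libraries at 0 h and rose to 10251 ± 2688 and 6871 ± 2092 FPKM, so no fold is given. The share of calls that were higher was 73.1% as deposited, 61.3% after median-of-ratios scaling and 47.4% after quantile normalization. The median of all genes shifted with it, from 0.74 log2 units to 0.36 and -0.13.

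**Figure D4:**
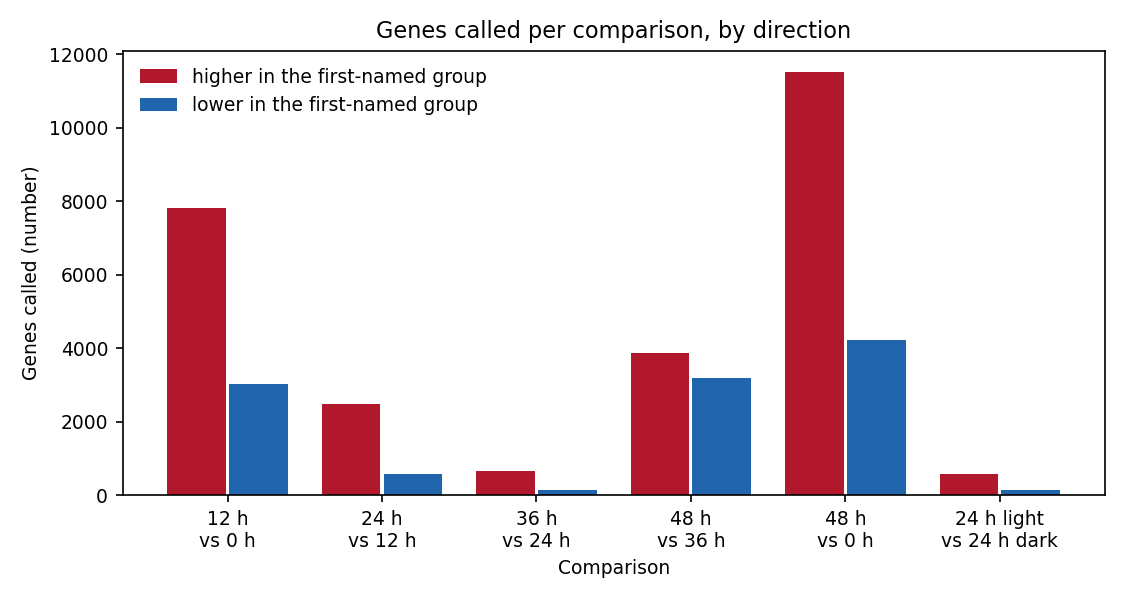
Number of genes called in each of the 6 comparisons (adjusted p under 0.05 and at least 1 log2 unit), as bars for genes higher and lower in the group named first. The step from 24 h to 36 h calls 824 genes, against 10842 from 0 h to 12 h and 7067 from 36 h to 48 h.

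The comparison of light with dark at 24 h asked how illumination alters expression at a fixed time. It called 727 of 23059 genes, 587 higher and 140 lower under light. Novel01618 was higher in light, at 27.7 ± 1.09 FPKM (SD, n = 3) against 0.0383, 0 and 0 in the dark libraries (log2 difference 4.82, SE 0.16, adjusted p = 7.14e-05). Novel01982 was listed at 0 in all dark libraries and at 13.9, 32.8 and 18.1 FPKM in light (adjusted p = 0.00112). Gbi11G2191 was lower in light, at 18.4 ± 3.92 against 75.7 ± 29.5 FPKM, a log2 difference of -1.93 (SE 0.29, adjusted p = 0.0166). Gbi13G2197 stood at 4.32 ± 0.916 against 18.4 ± 5.07 FPKM, a log2 difference of -1.84 (SE 0.25, adjusted p = 0.0105). Both of these lost their call without dark replicate 2 (adjusted p = 0.0746 and 0.0590), and Gbi11G2191 also without light replicate 1 (0.0664) or light replicate 3 (0.0732).

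The highest gene was Gbi10G1092 in the dark, at 11405 ± 2838 FPKM, and Gbi08G0896 in light, at 8667 ± 1075 FPKM (SD, n = 3). Gbi08G0896 stood nearly as high in the dark, at 11378 ± 4127 FPKM, and Gbi10G1092 at 7448 ± 916 FPKM in light. Both means were thus lower in light. In the time course the same 24 h light libraries put Gbi10G1092 first (5037 ± 653 against 4773 ± 583 FPKM). IDs that do not start with Gbi were 5.94% of the genes tested and 2.48% of those called. Light libraries held 23351 ± 301 genes at 1 FPKM or more and dark libraries 22177 ± 625, and the 100 highest genes took 18.04% ± 0.302 and 21.2% ± 2.33 of summed FPKM (exact permutation p = 0.1 for each, adjusted 0.109). Dark replicates 1, 2 and 3 stood at 23.7%, 20.9% and 19.1% on this measure. They lay at -77.6, -42.8 and -7.56 on the first principal component of this table (55.9% of the variance), against 36.9 to 47.9 for the light libraries. Across genes, the highest correlation of a dark with a light library (r = 0.960) exceeded the lowest between dark libraries (0.944) and between light libraries (0.953). The count of 727 rested on every library, being 355, 244 and 2153 without dark replicates 1, 2 and 3 and 251, 295 and 205 without light replicates 1, 2 and 3, and it was 312 with no filter. In light replicate 2, 213 genes lay at least 2 log2 units above both other light libraries, and in light replicate 1, 137 lay as far below both others, against at most 57 above and 41 below for the other libraries of this table. Of the 213 genes 31 were among those tested, and of the 137 genes 21. In the time-course table, which lists 156 of the 213 and 73 of the 137, 34 and 29 stood as far apart in the same library. Calls higher in light made up 80.7% as deposited, 67.3% after median-of-ratios scaling and 65.3% after quantile normalization, with the median of all genes at 0.13, -0.00 and -0.02 log2 units.

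More of the genes called higher in light rose from 12 h to 48 h than independent lists would give. The light comparison and that of 48 h with 12 h share no library. Of 562 genes higher in light and tested in both, 319 rose, 101 fell and 142 did neither, where independent lists would give 141, 102 and 319. Among 117 genes lower in light, 45 fell, 18 rose and 54 did neither, against 21.3, 29.3 and 66.4 for independent lists. Over all 20518 genes the relation was weak, with a Pearson r of 0.198 and a Spearman rho of 0.202 across genes. Of 10 splits of the light and dark libraries, 3 gave an r as large in size, the real one included, and the highest other reached 0.242. This r thus cannot be told apart from that of a chance split. The other splits called 0 genes, so the overlap counts could not be set against them. Genes are not independent either, so the counts do not tie the relation to light. The step from 12 h to 24 h shares the 24 h light libraries with the light response. There r was 0.0975 and the covariance 0.0393, where simulated unchanged groups gave 0.361 and 0.0289 from sharing alone. The simulated groups held no real change, so their r cannot be set against the observed r. On the covariance, the observed value was somewhat above the simulated one.

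**Figure D5:**
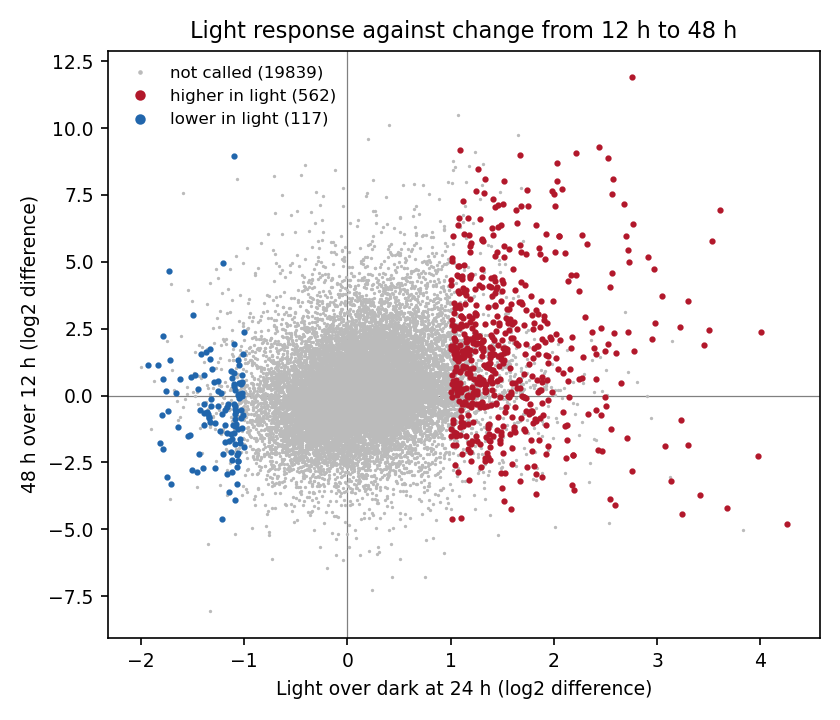
Log2 difference of 48 h over 12 h (vertical) against that of light over dark at 24 h (horizontal) for 20518 genes, a point each. Red marks 562 genes called higher in light, blue 117 called lower and grey the rest. Of the red points, 319 belong to genes that rose from 12 h to 48 h and 101 to genes that fell.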

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

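Settings were chosen before the data were examined except the fits without the 24 h libraries, which were chosen after seeing the data. Absolute depth is unknown, which limits what can be said of genes with low values. The numbers of genes changed at 12 h against 0 h, 24 h against 12 h, 48 h against 36 h, 48 h against 0 h and over time stayed within 1.5 times under every setting run except those named here. With no fold minimum the counts were 17016 (12 h against 0 h), 7039 (24 h against 12 h), 1708 (36 h against 24 h), 13791 (48 h against 36 h) and 1103 (light against dark). A limma fit of 24 h and 36 h alone called 0 genes, with 4944 at an unadjusted p under 0.05. Fewer libraries set the spread in such a fit, but that alone need not remove the calls. Under all alternatives, a fit of only the groups compared included, 24 h against 12 h kept at least 2682 genes and 48 h against 36 h at least 5677. The 36 h libraries correlated least with each other (median r 0.935, against 0.959 to 0.979 within the other times). The 824 calls thus rest on the spread shared with the other times. Light against dark fell to 312 genes with no filter, where the cause was not tested. Without the 24 h libraries the counts were 10832, 7039, 15734 and 20174 for 12 h against 0 h, 48 h against 36 h, 48 h against 0 h and over time.

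Leaving out each library gave 10488 to 10873 genes for 12 h against 0 h, 2744 to 3307 for 24 h against 12 h, 455 to 1402 for 36 h against 24 h, 6199 to 7707 for 48 h against 36 h, 14911 to 15765 for 48 h against 0 h, 205 to 2153 for light against dark and 19535 to 20571 over time. The 36 h against 24 h count moved by over 1.5 times without 24 h replicate 3 (529), 36 h replicate 2 (455) or 36 h replicate 3 (1402). The light against dark count did so without any of its 6 libraries. No pairing of the libraries by replicate number was seen: correlations of deviations between same-numbered libraries ran from -0.353 to 0.206, and in no comparison were all 3 above 0.1. The same holds for each number correlating best with its own. With 3 libraries per group a pairing is not ruled out. With the replicate number as a block the counts were 10841, 3044, 789, 7058, 15743, 701 and 20484, in the order above.

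The correlation of the light response with the change from 12 h to 48 h was 0.162 with a pseudocount of 0.1, 0.122 with no filter, 0.252 with a filter at 5 FPKM, 0.158 after quantile normalization and 0.0975 with 24 h against 12 h in its place. Leaving out each library gave 0.141 to 0.233. The cause was not tested.

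The ratio of genes detected at 0.1 FPKM was 1.18 for 12 h over 0 h, 1.04 for 24 h over 12 h and 1.25 for 48 h over 0 h, and for 48 h over 36 h it reversed, from 1.02 at 1 FPKM to 0.988. At 5 FPKM it was 1.06 for 48 h over 36 h, 1.46 for 48 h over 0 h and 1.09 for light over dark. The ratio of the top share was 0.452 (12 h over 0 h), 0.731 (36 h over 24 h), 1.79 (48 h over 36 h) and 0.452 (48 h over 0 h) for the top 10 genes. For the top 1000 genes it was 0.790, 0.934 (24 h over 12 h), 0.958, 1.03 and 0.724. These move because fewer or more genes are counted.

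For the 24 results on named genes, 521 of 539 alternatives kept direction and call, 18 lost the call and 0 reversed. All 18 concern 36 h against 24 h or light against dark. Novel01618 and Novel01982 have no value where a light library is left out, because they then reach 1 FPKM in too few libraries to be tested, and Gbi07G2774 has none where a 48 h library is.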

Other observations

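The tests on 0 h replicate 2, on the genes above both others in 36 h replicate 3 (except that for near-identical copies), on scaling and depth and on genes lower in light were chosen after the results were seen, as were the counts in the next 2 paragraphs and the shares from 12 h to 48 h or with a light or dark library left out; the splits of libraries and the tests of genes higher in light (12 h to 36 h) and of genes below both others in 36 h replicate 3 were fixed before their values were seen. Intervals of shares treat genes as independent draws, which they are not, so they cover the sampling of genes only.

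A small set of genes switched almost fully. In the time course 47 genes stood at 10 FPKM or more in all 48 h libraries and under 1 in all 12 earlier libraries, with Gbi07G2774 the highest. Another 110 genes stood at 100 FPKM or more in all 0 h libraries and under 1 in all 48 h libraries, with Gbi09G1925 the highest. At 0 h 30 genes stood at 10 FPKM or more in all libraries and under 1 in all 12 later libraries. Between the ends of the course, 21 genes stood at 10 FPKM or more in all 12 h libraries and under 1 in all 0 h and 48 h libraries, with Gbi12G3305 the highest, and 11 genes did so at 36 h. Of the genes tested for light, 1 of 68 in the set of 110 was higher and 0 were lower, 0 of 13 in the set of 21 were called, and 2 of 11 in the set of 11 were lower in light. No gene in the sets of 47 and 30 was tested for light.

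Called genes lay beside each other in ID number more often than random gene sets of the same size. Of 3867 genes higher at 48 h than 36 h, 27.1% had a neighbour with the next or previous number in the same set, against 19.1% on average and 21.3% at most in 1000 random draws (permutation p = 0.001, the smallest these draws can give, adjusted 0.001 over 13 sets). For 574 genes higher in light it was 8.71% against 3.21% (permutation p = 0.001, adjusted 0.001), while for 135 genes lower in light it was 2.96% against 0.805% (permutation p = 0.099, adjusted 0.099). That IDs in number order are neighbours on a chromosome was not tested. Among genes higher in light, 56.5% had their highest mean at 48 h once 24 h was left out, against 36.5% of all tested. Among genes lower in light 46.2% peaked at 36 h, against 19.1% of all tested.

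In 0 h replicate 2, 205 genes stood at least 2 log2 units above both other 0 h libraries and 60 below, against at most 22 and 16 for those other libraries. Of the 205, 94.1% were at least 1 log2 unit higher at 12 h (95% interval 90 to 96.9), compared with 31.2% of all tested genes, and 60% of the 60 were as much lower (11.5% of all tested), which is what a seed sample already slightly into germination would give. Reads mixed in from a later library would add a fixed fraction of that library's level, but over 56 genes the 90th percentile of this fraction was 63.0 times the 10th for 12 h, the smallest ratio among the 4 later times (95% interval 15.7 to 196). Mixing with a stage not sampled stays open. A candidate explanation, as a hypothesis, is therefore that germination was under way in this sample.

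In 36 h replicate 3, 207 genes stood at least 2 log2 units above both other 36 h libraries, with a median of 21.2 FPKM against 1.83 and 2.30, and 114 stood below, against at most 11 and 37 for those other libraries. A sample at an earlier stage, like 24 h, would leave most of the 207 higher at 24 h, but 22.7% were at least 1 log2 unit higher there than in 36 h replicates 1 and 2 (95% interval 17.2 to 29.02; 2.01% of all tested), so it is not their whole source. It stays open for that part and for the 114, of which 83.3% were as much lower at 24 h (95% interval 75.2 to 89.7, which reaches under the 80% set as needed; 4.88% of all tested), and replicate 3 (57.9 on the first principal component) lay nearer to the 24 h libraries (36.7 to 47.4) than replicates 1 and 2 did (75.3 and 86.6). Replicates 1 and 2 served both to choose the 207 and the 114 and as the reference, so all tested genes are no background of like level. Near-identical copies sharing reads account for few of the 207, as 2.42% had another ID with the same profile within 10% plus 0.1 FPKM. The 185 of them that were tested deviated together within the other 4 times, with a mean pairwise correlation of 0.293 against 0.0765 at most in 200 random sets of like level, and 37.8% had a neighbour by ID number in the set against 0.948% at random, so a set of transcripts that varies between samples of any time remains as a hypothesis.

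Most genes called for light were higher in light, and if dark seed were only behind in development at least 90% of these should increase from 12 h to 36 h. Of 573, 72.3% did (95% interval 68.4 to 75.9; 55.1% of all tested; 51.1% without dark replicate 3 and 74.1% to 81.6% without each of the other libraries) and 70.7% increased from 12 h to 48 h (54.2% of all tested), and a delay cannot be told apart for them because the interval passes the 75% set for excluding it. Of 130 genes lower in light, 33.1% decreased from 12 h to 36 h (44.5% of all tested; 13.5% without light replicate 1, 15.4% without dark replicate 2 and 45.5% without light replicate 2) but 63.8% decreased from 12 h to 48 h (45.6% of all tested; 61.4% to 80% with each library left out), and it cannot be told apart for them because the spans lie on opposite sides of all tested genes, except without light replicate 2. Abundant transcripts taking a larger share in the dark do not account for the whole excess, as 67.3% of calls were still higher in light after median-of-ratios scaling (59.3% to 93.0% with each library left out). Lower depth in the dark is unlikely, since light libraries were 1.02 times as deep as dark libraries, and a response to light itself stays open as untested.

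For each comparison of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. In each of the 6 comparisons 1 split, the real one, gave as many genes, with the highest of the others at 3 against 10842 (12 h against 0 h), 4 against 3063 (24 h against 12 h), 265 against 824 (36 h against 24 h), 2 against 7067 (48 h against 36 h), 1 against 15750 (48 h against 0 h) and 0 against 727 (light against dark). Every other split mixes libraries of both groups, so a real difference enters the spread and lowers its count. The low counts are therefore not those of unchanged groups. For the change over time 1 of 100 splits of the 15 libraries, the real one, gave 20521 genes and the highest other gave 9756. That is the smallest share 100 splits can give, so a random regrouping of these libraries is unlikely to call as many. For the correlation of the light response with the change from 12 h to 48 h, 3 of 10 splits gave a value as large in size as 0.198. The real split is among them, and 0.242 was the highest other. The correlation thus cannot be told apart from that of a chance split, and 10 splits are again too few for a share under 0.05.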
